A study of Mus musculus with 12 samples.

How the data were processed

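Gene expression was measured in mouse bone marrow cells (strain labelled C57/BL6/C3H) transduced with 1 of 4 retroviral constructs, with 3 biological replicates each. The constructs were the empty vector MIG, the fusion CALM-AF10, the same fusion without the part named OM-LZ (CALM-AF10 ΔOM-LZ), and a fusion of 2 fragments, CALM(400-648)+AF10(677-758), here named the minimal fusion. Per the labels, donor mice received 5-fluorouracil before marrow was taken, and the cells were stimulated in culture for 48 h. They were then transduced by overlay on irradiated virus-producing GFP+E86 cells (40 Gy) with cytokines and protamine sulfate (5 µg/ml), cultured further, and sorted for GFP. RNA was taken 96 h after transduction and hybridized to Affymetrix arrays after whole-transcript sense labelling. What a replicate number shares across constructs is not given in the sources used here.

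The deposited values are log2 intensities, 1 per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes. The version and the summarization and normalization methods are not given in the sources used here, so how the arrays were brought to a common scale is unknown. The log2 scale was read from the values, which ran from 2.883 to 14.272 over the arrays. Array medians ran from 6.581 to 6.686, and nothing was renormalized for the reported values. The number of arrays, 3 per group, limits the precision of every difference, and the width of the 95% intervals shows that limit gene by gene.

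The file held 35556 probe sets. A probe annotation table named genes for 23410 of them, and these were tested: 21789 carried 1 gene symbol and 1621 carried several. The other 12146 had no gene symbol, stayed out of these tests, and were tested apart. The 21789 probe sets stood for 19938 genes, of which 999 had more than 1 probe set. No probe set carried the symbol Picalm, alone or among several.

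Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). A single linear model held 1 mean per construct over the 12 arrays and left 8 residual degrees of freedom. All 6 pairs of constructs were compared, along with the mean of CALM-AF10 and the minimal fusion against the mean of MIG and CALM-AF10 ΔOM-LZ, and a moderated F test of any difference among the 4 groups. P values were two-sided and adjusted by the Benjamini-Hochberg method over the 23410 probe sets of a comparison, with a threshold of 0.05. A change is given as log2 fold change with its standard error (SE), and group levels as mean and standard deviation (SD). Group values are called non-overlapping where every array of one group lay above every array of the other. No replicate block entered the model. Whether replicate numbers pair the arrays was checked by correlating the deviations of same-numbered arrays from their group means. Between CALM-AF10 and ΔOM-LZ all 3 pairs correlated (r = 0.70 to 0.73), and for no other pair of constructs did every pair exceed 0.1. The pairing comes from the data and not from the labels, and for that comparison a paired fit of the 6 arrays is given beside the unpaired one, with 2 residual degrees of freedom.

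Gene lists were tested with camera from limma on the same fit, with its preset inter-gene correlation of 0.01, each list against all other genes, adjusted over the 25 lists of a comparison. The brightest probe set stood for a gene. Camera with a correlation estimated from the data, and the rotation test fry, were run beside it. For single members of a list, an adjusted p over the list alone was also computed. The lists covered the HOXA cluster, other HOX clusters, HOX cofactors, the Bmi1 neighbourhood, leukaemia self-renewal factors, and stem and progenitor markers. Others covered neutrophil primary and late granule genes, monocyte and macrophage, erythroid, megakaryocyte, mast cell, B cell, T and NK cell, dendritic, fibroblast and producer-line, and adipocyte and endothelial genes. The remaining lists were cell cycle, interferon response, p53 targets, immediate early genes, inflammatory cytokines, clathrin-mediated endocytosis, the DOT1L and AF10 complexes, and mouse sex-linked genes. A list score per array is the mean over the list's genes of the log2 value minus its mean over the 12 arrays.

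The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule named, among probe sets with 1 symbol that passed the adjusted p with non-overlapping groups, the 10 largest rises and the 10 largest falls of each comparison. It also named the members of the HOXA, HOX cofactor and Bmi1 neighbourhood lists, Picalm and Mllt10. From any other list discussed it named up to 4 members, those with the 2 highest and the 2 lowest moderated statistics. Where a gene had several probe sets the brightest stood for it, and a differing probe set is mentioned.

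Fold changes of pairs of comparisons were related by Pearson r over 19938 genes. Because comparisons against MIG share the MIG arrays, r was set beside 1000 simulated data sets of unchanged groups with each gene's residual spread.

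The procedure was tested on simulated data of the same size. Of 50 probe sets given a log2 change of 0.5 in the minimal fusion against MIG, 34% were called, and 78%, 94% and 94% at log2 changes of 1, 1.5 and 2. A further 12 unchanged probe sets were called, and none in the 3 comparisons without the minimal fusion. All of these changes were put into the same simulated data set, and with many changed probe sets the adjusted p is easier to pass. The shares called therefore do not carry over to comparisons with few or no calls, where a change of the same size is harder to call. With HOXA genes shifted as a group, the HOXA list was the 1 list to pass. Simulated genes varied independently of each other, so this could not show how often lists pass where genes vary together.

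Alternatives tried were a block for replicate number, quantile normalization, median centring, probe sets above the median level, trend and robust variance in eBayes, array weights, a fit of only the groups compared, 1 probe set per gene, the mean of all probe sets of a gene, a threshold of 0.01, a 2-fold minimum, and leaving out each array in turn. Testing all probe sets of the file and the paired fit were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.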

Results

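The 12 arrays did not sort by construct. Arrays of the same construct correlated with a mean r of 0.9834 over 12 pairs, and arrays of different constructs with 0.9835 over 54 pairs. The first principal component held 39.1% of the variance, of which 22% lay between constructs and 29.3% between replicate numbers. For the second component (17.5%) these shares were 21.7% and 28.9%, and for the fourth (9%) they were 53.6% and 18%. Scores on the first component correlated with the neutrophil primary granule list (r = 0.86), other HOX clusters (r = 0.81) and the cell cycle list (r = 0.78). They correlated inversely with p53 targets (r = −0.93), interferon response genes (r = −0.89), megakaryocyte genes (r = −0.85), mast cell genes (r = −0.84), sex-linked genes (r = −0.81) and the Bmi1 neighbourhood (r = −0.80). Differences between constructs were tested against this spread between replicates.

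The minimal fusion raised genes of the HOXA cluster, a run of developmental transcription factors active in blood stem cells. Hoxa9, a factor that keeps blood progenitors immature, stood at a log2 value of 8.67 (SD 0.20) in MIG arrays and 10.05 (SD 0.10) in minimal fusion arrays, a 2.62-fold rise. Hoxa6 rose 3.06-fold, Hoxa3 2.31-fold and Hoxa10, another HOX factor of myeloid progenitors, 2.26-fold. Outside the cluster, Cd27, a costimulatory receptor found on multipotent progenitors, rose 3.81-fold, and the homeobox factor gene Nkx2-3 rose 2.16-fold. The zinc finger gene Zscan25 rose 1.47-fold, and Ankrd37, an ankyrin repeat gene induced by low oxygen, fell 2.16-fold.

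These were the 8 probe sets past the threshold for the minimal fusion against MIG, 7 higher and 1 lower, and group values were non-overlapping for each. The log2 fold changes were 1.39 for Hoxa9 (SE 0.11, adjusted p = 0.00132), 1.61 for Hoxa6 (SE 0.16, adjusted p = 0.0111) and 1.93 for Cd27 (SE 0.23, adjusted p = 0.0359). Hoxa3 (1.21), Hoxa10 (1.18) and Ankrd37 (−1.11) each had an adjusted p of 0.0383, Nkx2-3 (1.11) one of 0.0451 and Zscan25 (0.56) one of 0.0484. Of all probe sets tested, 12.1% were non-overlapping between these groups, where chance gives 10%. The Hoxa9 rise passed without any 1 of the 12 arrays. The count was 1 without MIG replicate 3 or replicate 2 or 3 of the minimal fusion, 2 without CALM-AF10 replicate 1 or 3 or ΔOM-LZ replicate 1 or 3, and 4 without MIG replicate 1, ΔOM-LZ replicate 2 or minimal fusion replicate 1. The highest adjusted p without 1 array was 0.102 for Hoxa6 and 0.224 for Nkx2-3 (both without minimal fusion replicate 3), 0.155 for Cd27 and 0.22 for Hoxa3, Hoxa10 and Ankrd37 (all without minimal fusion replicate 2), and 0.26 for Zscan25 (without MIG replicate 3). A limma fit of these groups alone called 0 probe sets, with Hoxa9 and Hoxa6 at an adjusted p of 0.114. On all arrays 1781 had an unadjusted p under 0.05, where chance gives 1170.5, and trend and robust variance called 11. Zscan25 had 0.254 with trend and robust variance, and median centring gave 0.0557 for Zscan25 and Hoxa10.

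**Figure D1:**
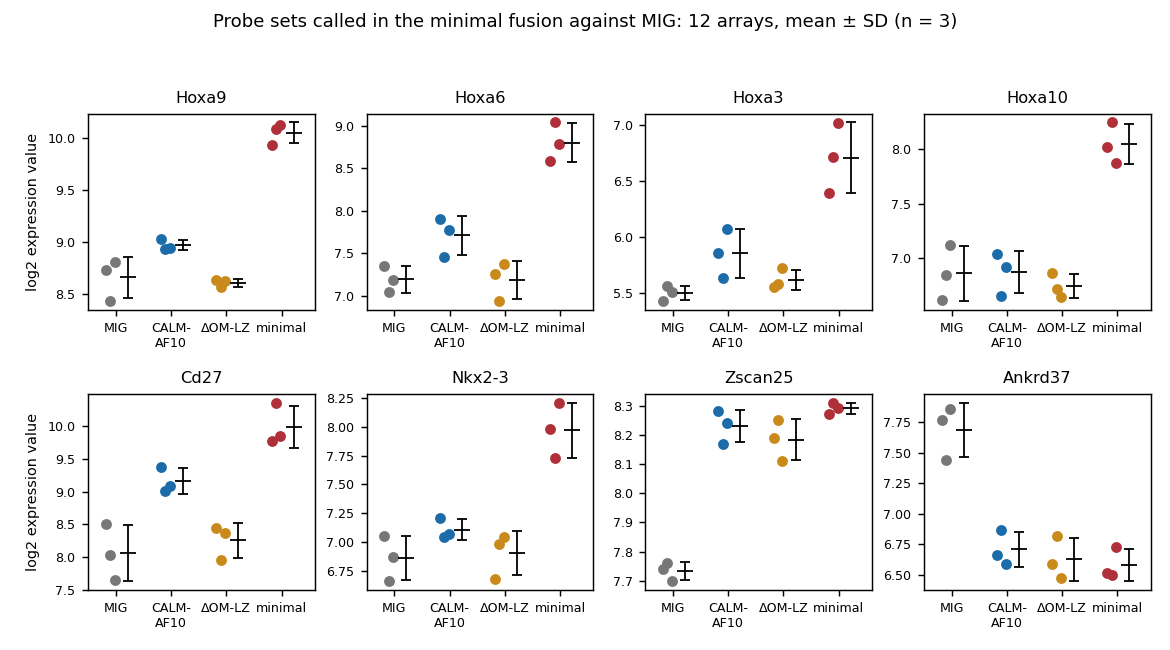
Log2 value (vertical axis) of the 8 genes called for the minimal fusion against MIG in each of the 12 arrays by construct, with mean and SD of 3 arrays. Hoxa9 lay at 10.05 (SD 0.10) in minimal fusion arrays and 8.67 (SD 0.20) in MIG arrays, while Zscan25 and Ankrd37 stood apart in MIG arrays from all fusion arrays.

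The HOXA list as a whole was higher in the minimal fusion than in MIG. All 10 measured members were higher, by a median log2 fold change of 1.16 (camera adjusted p = 1.09e-20), and this held with an estimated correlation (adjusted p = 0.00253) and by fry (adjusted p = 2.69e-05). Of its members, 4 passed over all genes and 8 adjusted over the list alone, which adds Hoxa2, Hoxa4, Hoxa5 and Hoxa7. Over all genes, Hoxa5 stood 1.47 higher (SE 0.20, adjusted p = 0.052), Hoxa7 1.15 (adjusted p = 0.33), Hoxa2 0.46 (adjusted p = 0.368) and Hoxa4 0.43 (adjusted p = 0.59), and Hoxa11 and Hoxa13 stood 0.27 and 0.25 higher (adjusted p = 0.718 and 0.686). The HOX cofactors, which help HOX proteins bind DNA, did not pass as a list (median −0.11, adjusted p = 0.301). Meis1, the cofactor most tied to leukaemia, differed by 0.31 (SE 0.41, adjusted p = 0.893).

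**Figure D2:**
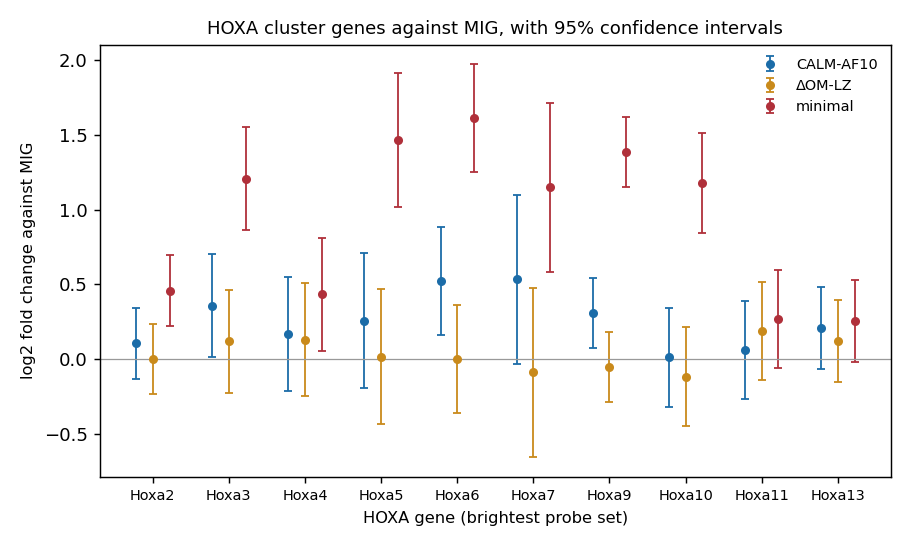
Log2 fold change against MIG (axis of values) with 95% confidence interval for 10 HOXA genes under CALM-AF10, CALM-AF10 ΔOM-LZ and the minimal fusion, 3 arrays per group. Hoxa9 was 1.39 higher under the minimal fusion, 0.31 under CALM-AF10 and −0.06 under ΔOM-LZ.

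Genes of megakaryocytes, late neutrophils, monocytes and mast cells stood lower in the minimal fusion than in MIG, and erythroid and neutrophil primary granule genes did not pass (camera adjusted p = 0.119 and 0.386). The platelet chemokine gene Ppbp stood 12-fold lower (SE of the log2 value 0.95) and Itgb3, a chain of the platelet fibrinogen receptor, 2.14-fold lower, both with an adjusted p of 0.415. The megakaryocyte list was lower by a median of 0.96 (camera adjusted p = 2.02e-09; adjusted p = 0.23 with an estimated correlation), with 0 members past the threshold over all genes and 8 lower when adjusted over the list alone. Late neutrophil genes were lower by 0.43 (adjusted p = 5.24e-05; 0.348 with an estimated correlation), monocyte and macrophage genes by 0.57 (adjusted p = 0.000114; 0.517 with an estimated correlation) and mast cell genes by 0.55 (adjusted p = 2.61e-06; 0.357 with an estimated correlation). Inflammatory cytokine genes were lower by 0.35 (adjusted p = 6.03e-06; 0.357 with an estimated correlation). In these last 4 lists 0 members passed over all genes, and adjusted over the list alone 1 did, Nos2, the macrophage nitric oxide synthase gene (log2 fold change −0.93). The MIG arrays differed among themselves in these genes. MIG replicates 1, 2 and 3 had mast cell scores of −0.27, 0.10 and 1.35 and megakaryocyte scores of −0.13, 0.81 and 0.95, while the highest minimal fusion array had −0.22 and −0.21. The late neutrophil score of MIG replicate 3 (−0.50) and its monocyte score (−0.55) lay within the range of the minimal fusion arrays. The monocyte call was lost without MIG replicate 2 (adjusted p = 0.2).

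Lists of progenitor and leukaemia self-renewal genes stood higher in the same comparison, with members in both directions. The leukaemia self-renewal list, which includes Hoxa9 and Hoxa10, was higher by a median of 0.18 (camera adjusted p = 7.86e-07; adjusted p = 0.23 with an estimated correlation; fry adjusted p = 0.043). Of its members 2 passed over all genes, and adjusted over the list alone 7 were higher, among them the transcriptional cofactor gene Eya1, and 1 lower, Id2, an inhibitor of differentiation factors (log2 fold change −1.57, adjusted p = 0.555 over all genes). Stem and progenitor markers were higher by 0.12 (adjusted p = 0.0188; 0.517 with an estimated correlation), with Cd27 past the threshold over all genes and Sox4, Lmo2 and Cd27 adjusted over the list alone. Lmo2, a stem cell transcription adaptor gene, stood 0.59 higher (adjusted p = 0.394 over all genes). Of the 22 stem and progenitor markers 8 stood lower, among them the angiopoietin receptor gene Tek by 1.17 (adjusted p = 0.604) and Gata2, a stem cell transcription factor gene, by 0.51 (adjusted p = 0.803). The stem and progenitor call was lost without MIG replicate 1 (adjusted p = 0.202), MIG replicate 2 (0.279) or minimal fusion replicate 1 (0.138).

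**Figure D3:**
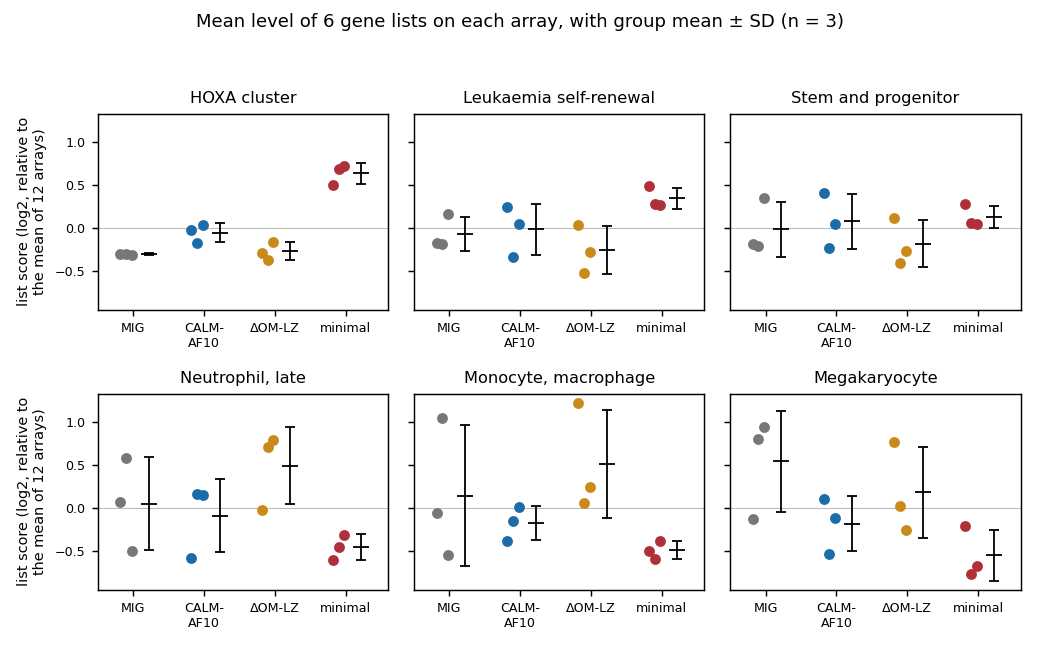
List score (log2 relative to the mean of 12 arrays, vertical axis) of 6 gene lists in each array by construct, with mean and SD of 3 arrays. The HOXA score was 0.63 (SD 0.12) in minimal fusion arrays against −0.31 (SD 0.01) in MIG arrays, and the late neutrophil score ran from −0.46 in minimal fusion to 0.49 in ΔOM-LZ arrays.

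Another 5 lists passed with camera's preset correlation between the minimal fusion and MIG and did not hold with an estimated one. Other HOX clusters were higher by 0.08 (adjusted p = 0.0188; 0.602 with an estimated correlation). P53 targets were lower by 0.22 (adjusted p = 0.0188; 0.517 with an estimated correlation), interferon response genes by 0.15 and immediate early genes by 0.39 (both adjusted p = 0.0381; 0.602 with an estimated correlation), and clathrin-mediated endocytosis genes by 0.10 (adjusted p = 0.0381; 0.348 with an estimated correlation). Without MIG replicate 3 adjusted p became 0.967 for the immediate early and interferon lists, 0.472 for p53 targets and 0.0595 for other HOX clusters. Without minimal fusion replicate 1 it became 0.172 for the clathrin list and 0.219 for the immediate early list, and without MIG replicate 1, 0.15 for the clathrin list. Without minimal fusion replicate 2 it became 0.744 for immediate early genes, 0.378 for interferon genes and 0.0842 for p53 targets, and without replicate 3, 0.339 for other HOX clusters, 0.0983 for interferon genes and 0.0555 for the clathrin list. Quantile normalization gave 0.0679 for other HOX clusters, 0.0631 for interferon genes, 0.0852 for immediate early genes and 0.0883 for the clathrin list. The 12 lists that did not pass were HOX cofactors, the Bmi1 neighbourhood, neutrophil primary granule, erythroid, B cell, T and NK cell, dendritic, fibroblast and producer-line, adipocyte and endothelial, cell cycle, DOT1L and AF10 complex and sex-linked genes, with adjusted p from 0.119 to 0.838. In 3 of them median, mean and test differed in sign: B cell (median 0.02, mean −0.08, test lower), T and NK cell (0, −0.10, test higher) and fibroblast genes (0.01, −0.06, test lower).

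CALM-AF10 changed no probe set against MIG by limma. The smallest adjusted p was 0.526, 1231 probe sets had an unadjusted p under 0.05 where chance gives 1170.5, and trend and robust variance also gave 0. Cd27 stood 1.10 higher (SE 0.23, adjusted p = 0.543) and Sox4, a progenitor transcription factor gene, 0.54 higher (adjusted p = 0.738). Among HOXA genes Hoxa7 stood 0.53, Hoxa6 0.52, Hoxa3 0.36, Hoxa9 0.31 (SE 0.11) and Hoxa10 0.01 higher, with adjusted p of 0.767 for Hoxa6 and 0.833 for Hoxa9. Eosinophil granule genes stood lower, Epx by 1.20 (adjusted p = 0.738) and Prg2 by 1.08 (adjusted p = 0.698). This was not particular to CALM-AF10: under ΔOM-LZ their log2 fold changes against MIG were −0.805 and −0.981. Minimal fusion means were 6.212 and 6.339, against 6.762 (SD 0.839) and 7.055 (SD 0.716) in MIG arrays. Without MIG replicate 2 the count was 1.

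As lists, HOXA genes were higher in CALM-AF10 than in MIG and megakaryocyte genes lower. All 10 HOXA members stood higher, by a median of 0.23 (camera adjusted p = 0.000267; adjusted p = 0.422 with an estimated correlation; fry 0.28), with 0 members past the threshold over all genes or adjusted over the list alone. Megakaryocyte genes were lower by 0.67 (adjusted p = 1.07e-06; 0.629 with an estimated correlation), and both of these calls passed without any 1 array. Mast cell genes were lower by 0.40 (adjusted p = 2.54e-05; 0.7 with an estimated correlation), cell cycle genes by 0.22 (adjusted p = 0.000182; 0.848), monocyte genes by 0.17 (0.0164; 0.848), interferon genes by 0.16 (0.0184; 0.848) and erythroid genes by 0.18 (0.0224; 0.7), and stem and progenitor markers were higher by 0.11 (0.0477; 0.848). Adjusted over the list alone, Cd27 and the p53 target Aen were higher and Nos2 lower, and 0 members of any list passed over all genes. Calls were lost without MIG replicate 1 (cell cycle 0.626, stem 0.311), MIG replicate 2 (monocyte 0.737, stem 0.737), MIG replicate 3 (erythroid 0.985, interferon 0.985, mast cell 0.397), CALM-AF10 replicate 1 (stem 0.826, monocyte 0.203, erythroid 0.055), replicate 2 (interferon 0.713, erythroid 0.052) and replicate 3 (cell cycle 0.284, stem 0.0622). The stem list also lost its call without ΔOM-LZ replicate 3 (0.0521) or minimal fusion replicate 3 (0.0505), and quantile normalization gave 0.057 for it and 0.0518 for erythroid genes. The number of lists passing was 8, or 5 without CALM-AF10 replicate 1.

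CALM-AF10 ΔOM-LZ, which lacks the stretch of AF10 that binds the histone methyltransferase DOT1L, left HOXA genes near their level in MIG. Hoxa9 differed by −0.06 (SE 0.11, 95% interval −0.29 to 0.18), Hoxa10 by −0.12, Hoxa7 by −0.09 and Hoxa5 by 0.02, and the HOXA list did not pass (median 0.01, camera adjusted p = 0.631). The neutrophil surface gene Ly6g stood 1.35 higher (SE 0.49) and the chemokine receptor gene Cxcr2 0.76 higher, each with an adjusted p of 0.999. By limma 0 probe sets changed against MIG, with 927 at an unadjusted p under 0.05 (chance gives 1170.5) and 0 with trend and robust variance. Without MIG replicate 2 the count was 4.

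Late neutrophil genes were higher as a list in ΔOM-LZ than in MIG by a median of 0.39 (camera adjusted p = 0.00114; adjusted p = 0.733 with an estimated correlation), and monocyte genes by 0.40 (adjusted p = 0.0102; 0.842). Lower as lists were megakaryocyte genes by 0.33 (0.011; 0.733), cell cycle genes by 0.20 (0.00699; 0.842), interferon genes by 0.20 (0.00722; 0.733), leukaemia self-renewal factors by 0.12 (0.0218; 0.733) and DOT1L and AF10 complex genes by 0.09 (0.0218; 0.733), the values in brackets being the adjusted p with the preset and with an estimated correlation. None of these 7 calls held with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone Nos2 was lower. Without MIG replicate 3 the number of lists passing was 3, and monocyte (0.729), interferon (0.729), leukaemia (0.493), megakaryocyte (0.493) and DOT1L and AF10 complex genes (0.417) lost their calls. Calls were also lost without MIG replicate 1 (monocyte 0.129, cell cycle 0.938), MIG replicate 2 (megakaryocyte 0.133), ΔOM-LZ replicate 1 (monocyte 0.795, cell cycle 0.469), replicate 2 (leukaemia 0.595, interferon 0.42, DOT1L 0.317, megakaryocyte 0.11) and replicate 3 (neutrophil late 0.0711, megakaryocyte 0.332), and quantile normalization gave 0.0845 for leukaemia and 0.114 for DOT1L and AF10 complex genes.

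Against ΔOM-LZ, the minimal fusion raised Hoxa6 3.06-fold, Hoxa9 2.72-fold and Hoxa10 2.46-fold. It also raised Mecom, a stem cell factor gene activated in some myeloid leukaemias, by 2.35-fold on the dimmer of its probe sets. These were the 4 probe sets called (adjusted p = 0.0111, 0.000886, 0.0282 and 0.0473), all higher. The brighter Mecom probe set stood 4.22-fold higher (log2 fold change 2.08, SE 0.38) and did not pass (adjusted p = 0.32). Against MIG the dimmer probe set stood 2.05-fold higher (adjusted p = 0.0639) and the brighter 2.77-fold (adjusted p = 0.405). Against CALM-AF10 they stood 2.01-fold and 3.28-fold higher, and neither passed. Of the genes near the threshold against ΔOM-LZ, Cd27 stood 1.74 higher (adjusted p = 0.0584), Hoxa5 1.45 (0.0733) and Hoxa3 1.09 (0.0738). Only Hoxa9 passed without any 1 array: the count was 1 without ΔOM-LZ replicate 1 or 2 or minimal fusion replicate 2 or 3, and 2 without MIG replicate 2, CALM-AF10 replicate 1 or 3, ΔOM-LZ replicate 3 or minimal fusion replicate 1. The highest adjusted p without 1 array was 0.0796 for Hoxa6 (without minimal fusion replicate 2), 0.223 for Hoxa10 and 0.249 for Mecom (both without ΔOM-LZ replicate 2). A limma fit of these groups alone called 0 (Hoxa9 adjusted p = 0.0556). On all arrays 960 had an unadjusted p under 0.05, where chance gives 1170.5. Median centring gave 0.0561 for Hoxa10 and 0.0729 for Mecom, and quantile normalization gave 0.107 for Mecom. The mean of the Mecom probe sets did not pass, and trend and robust variance called 8.

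Here 3 lists passed with a preset and an estimated correlation. HOXA genes were higher by a median of 1.16 (camera adjusted p = 2.64e-25; 0.00123 with an estimated correlation), with 3 members past the threshold over all genes and 7 adjusted over the list alone. Leukaemia self-renewal factors were higher by 0.35 (adjusted p = 1.12e-15; 0.0289 with an estimated correlation; 2 members over all genes, 8 adjusted over the list alone). The 2 members were Hoxa9 and Hoxa10, which are also in the HOXA list. The leukaemia list was not tested without them, so its call is not separate from the HOXA call. Late neutrophil genes were lower by 0.97 (adjusted p = 1.79e-16; 0.0289 with an estimated correlation; 0 members over all genes, 5 adjusted over the list alone), among them Ly6g (log2 fold change −2.22) and Cxcr2 (−1.78). Monocyte genes were lower by 0.99 (9.13e-14; 0.156), inflammatory genes by 0.65 (2.29e-12; 0.104), megakaryocyte genes by 0.46 (9.68e-07; 0.196), mast cell genes by 0.63 (1.01e-05; 0.354), immediate early genes by 0.35 (0.000409; 0.495), clathrin genes by 0.08 (0.00244; 0.104) and p53 targets by 0.29 (0.00771; 0.498). Stem and progenitor markers were higher by 0.32 (1e-06; 0.145) and cell cycle genes by 0.33, all 34 of them (1.15e-07; 0.559), the values in brackets being adjusted p with the preset and with an estimated correlation. Among these 9 lists 0 members passed over all genes, and adjusted over the list alone 3 stem and progenitor markers were higher (Sox4, Lmo2 and Cd27), and 3 monocyte genes and 1 inflammatory gene lower. Without ΔOM-LZ replicate 1 adjusted p was 0.472 for p53 targets and 0.091 for clathrin genes, without ΔOM-LZ replicate 3 it was 0.0763 for p53 targets, and without minimal fusion replicate 2 it was 0.198 for immediate early genes. The cell cycle score of ΔOM-LZ replicate 2, at 0.27, lay above those of minimal fusion replicates 1 and 3, at −0.05 and 0.18.

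The minimal fusion and full CALM-AF10 differed in Hoxa9, 2.12-fold higher in the minimal fusion (log2 fold change 1.08, SE 0.11, adjusted p = 0.0161). This was the 1 probe set called. Hoxa10 stood 1.17 higher (adjusted p = 0.113), Hoxa6 1.09 (0.283) and Hoxa5 1.21 (0.469). The Hoxa9 call was lost in a fit of these groups alone (adjusted p = 0.274) and in 7 of the 12 fits without 1 array, those without any 1 CALM-AF10 or minimal fusion array or ΔOM-LZ replicate 3, with the highest adjusted p, 0.173, without CALM-AF10 replicate 3. The HOXA list was higher by a median of 0.73 (camera adjusted p = 4.22e-26; 0.0011 with an estimated correlation), with 1 member past the threshold over all genes and 6 adjusted over the list alone.

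All 34 cell cycle genes stood higher in the minimal fusion than in CALM-AF10, by a median of 0.36 (camera adjusted p = 1.87e-12; adjusted p = 0.76 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Cell cycle scores were −0.38, 0.43 and −0.51 in CALM-AF10 replicates 1, 2 and 3 and −0.05, 0.48 and 0.18 in those of the minimal fusion, so CALM-AF10 replicate 2 lay above 2 minimal fusion arrays. Leukaemia self-renewal factors were higher by 0.06 (adjusted p = 1.08e-06; 0.341 with an estimated correlation; 1 member over all genes, Hoxa9, and 4 adjusted over the list alone). Lower were inflammatory genes by 0.42 (1.06e-06; 0.58), among them the acute-phase gene Saa3 (−2.33), late neutrophil genes by 0.28 (0.000415; 0.599), immediate early genes by 0.29 (0.0114; 0.826) and megakaryocyte genes by 0.32 (0.0154; 0.826), the values in brackets being adjusted p with the preset and with an estimated correlation. Calls were lost without CALM-AF10 replicate 1 (megakaryocyte 0.382), replicate 2 (leukaemia 0.0648) or replicate 3 (immediate early 0.457), and without minimal fusion replicate 1 (immediate early 0.138), replicate 2 (immediate early 0.796, megakaryocyte 0.271) or replicate 3 (megakaryocyte 0.079).

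Between CALM-AF10 and ΔOM-LZ, limma called 0 probe sets, 0 also with trend and robust variance, with a smallest adjusted p of 1. An unadjusted p under 0.05 was found for 528, where chance gives 1170.5. Hoxa6 stood 0.52 and Hoxa9 0.36 higher (SE 0.16 and 0.11) in CALM-AF10, and these were the members past the threshold adjusted over the HOXA list alone. The HOXA list was higher by a median of 0.18 (camera adjusted p = 0.000579; adjusted p = 0.246 with an estimated correlation). Late neutrophil genes were lower by 0.65 in CALM-AF10, all 22 of them (4.83e-09; 0.246), with Cxcr2 at −1.28, and monocyte genes by 0.58 (5.29e-10; 0.294). Late neutrophil scores of CALM-AF10 replicates 2 and 3, at 0.17 and 0.15, lay above that of ΔOM-LZ replicate 1, at −0.02. Each CALM-AF10 array lay below the ΔOM-LZ array of its own number. Stem and progenitor markers were higher by 0.25 (5.69e-06; 0.255), leukaemia self-renewal factors by 0.25 (2.45e-06; 0.246) and DOT1L and AF10 complex genes by 0.08 (0.0343; 0.531). Lower were megakaryocyte genes by 0.34 (0.00671; 0.531), mast cell genes by 0.16 (0.000579; 0.531), inflammatory genes by 0.18 (0.00402; 0.531) and clathrin genes by 0.06 (0.0383; 0.288), the values in brackets being adjusted p with the preset and with an estimated correlation, and none held with the latter. Calls were lost without CALM-AF10 replicate 1 (clathrin 0.112, DOT1L 0.0532), replicate 2 (inflammatory 0.528, megakaryocyte 0.472, mast cell 0.237, clathrin 0.103) or replicate 3 (DOT1L 0.494), and without ΔOM-LZ replicate 1 (megakaryocyte 0.666, inflammatory 0.579, clathrin 0.579, mast cell 0.159, DOT1L 0.0539), replicate 2 (DOT1L 0.426) or replicate 3 (clathrin 0.0529), and quantile normalization gave 0.238 for DOT1L and AF10 complex genes.

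Arrays of CALM-AF10 and ΔOM-LZ with the same replicate number deviated together (r = 0.70 to 0.73). These constructs were picked by that correlation out of 6 pairs of constructs, so p values of the paired fit can be too small. A paired fit of these 6 arrays, with the number as a block, called 1 probe set, Prss34, a protease gene of basophils, 3.15-fold lower in CALM-AF10 (log2 fold change −1.66, SE 0.07, adjusted p = 0.031, against 1 unpaired). The paired fit gave 3330 probe sets at an unadjusted p under 0.05 and 6 calls with trend and robust variance. The Prss34 call was lost without pair 1 (adjusted p = 0.36), pair 2 (0.279) or pair 3 (0.281). Paired, Hoxa6 had an adjusted p of 0.229, Hoxa9 of 0.231 and Cxcr2 of 0.229. Of the lists, 14 passed with the preset correlation and 0 with an estimated one (fry 2). The 10 unpaired list calls were among them, late neutrophil genes with the smallest adjusted p (4.41e-16; 0.28 with an estimated correlation; fry 0.0244), and sex-linked (0.0277; 0.566; fry 0.0244), neutrophil primary granule (0.025; 0.667), erythroid (0.048; 0.667) and B cell genes (0.0476; 0.566) were added.

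Averaged over CALM-AF10 and the minimal fusion, and set against the average of MIG and ΔOM-LZ, Cd27 rose 2.67-fold (adjusted p = 0.0252), Hoxa6 2.09-fold (adjusted p = 0.0212) and Hoxa9 1.83-fold (adjusted p = 0.00429). These 3 were the probe sets called. Hoxa9 passed without any 1 array, and the count was 1 without MIG replicate 3, CALM-AF10 replicate 1 or 3, ΔOM-LZ replicate 1 or 2, or minimal fusion replicate 2 or 3, and 6 without CALM-AF10 replicate 2. The highest adjusted p was 0.109 for Hoxa6 without CALM-AF10 replicate 3 and 0.116 for Cd27 without CALM-AF10 replicate 1. Median centring gave 0.0638 for both, and replicate number as a block gave 0.0865 for both. The F test of any difference called Hoxa9 (adjusted p = 0.00262) and Hoxa6 (adjusted p = 0.0292), 0 without minimal fusion replicate 2 or 3 and 3 without CALM-AF10 replicate 2. Of 12 lists that passed for the averages, HOXA held with an estimated correlation (median 0.69, camera adjusted p = 1.5e-18; 0.00372 with an estimated correlation; 2 members over all genes, 7 adjusted over the list alone), and leukaemia self-renewal factors passed by fry (0.0179) and not with an estimated correlation (adjusted p = 0.108). The leukaemia list includes Hoxa9, called here, and Hoxa10, so it is not separate from the HOXA list.

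Changes of CALM-AF10 and of the minimal fusion against MIG correlated with r = 0.749 over 19938 genes. Shared MIG arrays alone gave a mean r of 0.473 in simulation, and 264 of 1000 simulated sets reached the observed value. Between CALM-AF10 against MIG and the minimal fusion against ΔOM-LZ, which share no array, r was 0.38, reached by 250 of 1000 simulated sets. Simulated arrays were drawn independently of each other, while same-numbered CALM-AF10 and ΔOM-LZ arrays deviated together in the data. Sharing no array therefore does not make these comparisons independent, and that share does not settle whether chance gave the value. The first r was 0.42 without CALM-AF10 replicate 2, and the other 0.161 without MIG replicate 2, 0.206 without CALM-AF10 replicate 2 and 0.218 without ΔOM-LZ replicate 1. Of the probe sets called against MIG, 0 were shared, since CALM-AF10 had none by limma (1231 at an unadjusted p under 0.05, 0 with trend and robust variance), and 3 HOXA genes, Hoxa6, Hoxa9 and Hoxa10, were called for the minimal fusion against both MIG and ΔOM-LZ. A gene past the threshold under the minimal fusion and not under CALM-AF10 was taken to differ between them where the direct comparison passed, which held for Hoxa9.

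The mouse genes named in the fusion could be read in part. Mllt10, the mouse AF10 gene, stood 0.16, 0.13 and 0.12 lower than in MIG under CALM-AF10, ΔOM-LZ and the minimal fusion (SE 0.12 each). No probe set carried the symbol of Picalm, the mouse CALM gene. Bmi1, a Polycomb gene near Mllt10, stood 0.24 higher than in MIG under the minimal fusion (SE 0.21, adjusted p = 0.833) and 0.27 under CALM-AF10. Its neighbourhood list did not pass in any comparison of the fit over 12 arrays, and neither did the HOX cofactor, neutrophil primary granule, B cell, T and NK cell, dendritic, fibroblast and producer-line, adipocyte and endothelial or sex-linked lists.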

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

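The tests of replicate number and of construct on the first principal component were chosen after the values were seen, as were the paired fit and the testing of probe sets without a gene name. The splits and the tests of the HOXA rise were chosen before.

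Differences appeared among the 12146 probe sets that carry no gene symbol and enter no comparison of the report. Tested on their own, 21 of them changed between the minimal fusion and MIG, 11 between the minimal fusion and ΔOM-LZ, 5 between the minimal fusion and CALM-AF10, 2 between ΔOM-LZ and MIG, and 1 between CALM-AF10 and MIG. Of the 21, 20 were higher in the minimal fusion, by a median log2 fold change of 2.11 and a range of 0.98 to 3.43, and the same 20 had medians of 0.42 in CALM-AF10 and 0.26 in ΔOM-LZ against MIG. All 20 carry identifiers below the first probe set with a listed gene, as do 6617 of the 12146. Probe set 10468877, singled out after its values were seen, had log2 changes against MIG of −4.64 in CALM-AF10, −4.35 in ΔOM-LZ and −4.56 in the minimal fusion, with MIG arrays at 9.05, 8.94 and 9.43. What these probe sets measure, and whether they are control or background probe sets of the array, is not given in the sources used here, so these values are not read as gene expression.

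For each pair of constructs, the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of those 10 splits, as many probe sets as in the real one came from 1 for the minimal fusion against MIG (real count 8, highest other 0), 1 against ΔOM-LZ (4, highest other 0) and 1 against CALM-AF10 (1, highest other 0). For CALM-AF10 against MIG, ΔOM-LZ against MIG and CALM-AF10 against ΔOM-LZ it was 10 of 10. The real count by limma was 0 in each, with a highest other of 0. In the same order 1231, 927 and 528 had an unadjusted p under 0.05, where chance gives 1170.5, and trend and robust variance called 0. For gene lists the splits reaching the real count were 8 for CALM-AF10 against MIG (real 8, highest other 18), 7 for ΔOM-LZ against MIG (7, 16), 3 for the minimal fusion against MIG (13, 13), 5 for CALM-AF10 against ΔOM-LZ (10, 16), 1 for the minimal fusion against ΔOM-LZ (12, 11) and 6 against CALM-AF10 (7, 13). Where same-numbered arrays pair, between CALM-AF10 and ΔOM-LZ, the 3 other splits that part all 3 pairs gave 6 to 9 lists, and the 6 that part 1 pair gave 3 to 16. In the paired fit the real split gave 1 probe set and 14 lists, and the 3 others that part all pairs gave 0 probe sets by limma and 6 to 11 lists. Among 100 regroupings of the 12 arrays, 4 gave as many probe sets as the real one for the averages of 2 constructs each (3, highest other 1328), the real one included, a share under 0.05. These regroupings do not keep same-numbered CALM-AF10 and ΔOM-LZ arrays apart, which lie on opposite sides of this comparison, so that share does not settle whether chance gave the count. Chance was not excluded for the F test, with 8 of 100 (real count 2, highest other 291), nor for the lists of the averages, with 21 of 100 (12, highest other 15). A regrouping that called 1328 probe sets, many times the real count, points to a structure of the arrays that the constructs do not follow.

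The 12 arrays resembled each other across constructs as much as within them, and if the replicate number marked a shared marrow or day, arrays of the same number should deviate together, and an exact one-sided permutation test of this gave p = 0.19 over 216 assignments (mean r 0.09). Among the 3 fusions alone the exact p was 0.056 over 36 assignments (mean r 0.41), where the smallest p possible was 0.028. Construct, the biological grouping, explained 22% of the first component, with a permutation p of 0.518, and replicate number 29.3%. CALM-AF10 and ΔOM-LZ arrays of the same number did deviate together (mean r 0.72), the highest of 6 assignments of the numbers, the next being 0.05. These 6 assignments are too few for a share under 0.05, and this pair of constructs was picked after all pairs of constructs were seen. None of these tests settled what the structure follows over all 4 constructs.

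The HOXA rise in the minimal fusion could come from a larger share of immature cells, from fewer maturing cells, or from a rise of the whole chromosomal region, and was tested against each. The mean HOXA difference from MIG was 0.94 (SE 0.08), 0.94 (SE 0.09) with the stem and progenitor score as a covariate, and 0.96 (SE 0.11) with the late neutrophil and monocyte scores as covariates. The stem and progenitor score itself was −0.02 (SD 0.32) in MIG arrays and 0.13 (SD 0.13) in minimal fusion arrays. A score so close between the groups could take up little of the rise. The 10 measured genes flanking the cluster had a median change of 0.02 (95% bootstrap interval −0.22 to 0.28). They were not all flat: single genes ran from −0.84 (Jazf1, SE 0.39) to 0.40 (Skap2, SE 0.16), and none passed the threshold. None of the 3 accounted for the rise by the criteria set beforehand. The stem and progenitor score could hardly have met its criterion, so that test does not decide on a larger share of immature cells. A direct effect of the minimal fusion on the cluster remains a hypothesis, since it was found and tested on the same arrays and marker scores are a partial measure of cell makeup.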

How the results depend on the processing

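Testing all probe sets of the file and the paired fit of CALM-AF10 and ΔOM-LZ were chosen after the data were seen; the other alternatives were chosen before. The averages are those of CALM-AF10 and the minimal fusion against MIG and ΔOM-LZ. Values without 1 array are lowest to highest over the 12 arrays.

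With replicate number as a block, the minimal fusion against MIG had 1 probe set called in place of 8 (Hoxa9, with the other 7 at adjusted p of 0.0553 to 0.137). The minimal fusion against CALM-AF10 had 0 in place of 1 by limma, with Hoxa9 at 0.0767. Without the block 422 had an unadjusted p under 0.05 there, where chance gives 1170.5, and trend and robust variance called 1. With the block the averages had 1 in place of 3 and the F test 1 in place of 2. Over all 4 constructs, 7 of 18 pairs of the same number deviated together with r above 0.1, from −0.6 to 0.73, and 7 of 12 arrays lay closest to an array of their own number, so the numbers do not pair all samples. In CALM-AF10 against ΔOM-LZ all 3 pairs did, and a replicate block in a fit of those 6 arrays called 1 in place of 0 and 14 lists in place of 10. The block over all arrays changed no other count by over 1.5 times, though Hoxa10 lost its call for the minimal fusion against ΔOM-LZ (adjusted p = 0.106). Array weights gave 13 for the minimal fusion against MIG, 1 for ΔOM-LZ against MIG, 16 for the averages and 4 for the F test. A fit of only the groups compared gave 0 for the minimal fusion against MIG, against ΔOM-LZ (in place of 4) and against CALM-AF10. Median centring gave 2 for the minimal fusion against ΔOM-LZ, 1 for the averages and 1 for the F test, and quantile normalization 4 for the F test. Trend and robust variance gave 8 for the minimal fusion against ΔOM-LZ. Testing all 35556 probe sets gave 1 for CALM-AF10 against MIG, 2 for ΔOM-LZ against MIG, 20, 17 and 3 for the minimal fusion against MIG, ΔOM-LZ and CALM-AF10, 5 for the averages and 12 for the F test. An adjusted p below 0.01 left 1 for the minimal fusion against MIG, 1 against ΔOM-LZ, 0 against CALM-AF10, 1 for the averages and 1 for the F test. The cause of these shifts was not tested, apart from the fewer arrays or the stricter threshold that the alternatives themselves bring. Every other setting kept the count within 1.5 times, and CALM-AF10 against ΔOM-LZ stayed at 0 by limma under every alternative but the paired fit. There 528 had an unadjusted p under 0.05 in the main fit, where chance gives 1170.5, and trend and robust variance called 0.

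Without 1 array, the counts ran from 1 to 9 for the minimal fusion against MIG, 1 to 5 against ΔOM-LZ, 0 to 1 against CALM-AF10, 0 to 1 for CALM-AF10 against MIG, 0 to 4 for ΔOM-LZ against MIG, 0 to 0 for CALM-AF10 against ΔOM-LZ, 1 to 6 for the averages and 0 to 3 for the F test. Lists ran from 5 to 9 for CALM-AF10 against MIG, 3 to 9 for ΔOM-LZ against MIG, 9 to 13 for the minimal fusion against MIG, 8 to 13 for CALM-AF10 against ΔOM-LZ, 12 to 14 and 6 to 10 for the minimal fusion against ΔOM-LZ and CALM-AF10, and 9 to 14 for the averages. The correlation of 0.749 ran from 0.42 to 0.854 and that of 0.38 from 0.161 to 0.482, and the overlap of calls against MIG from 0 to 1.

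An estimated correlation left 0 lists for CALM-AF10 and for ΔOM-LZ against MIG, 1 for the minimal fusion against MIG, 0 for CALM-AF10 against ΔOM-LZ, 3 for the minimal fusion against ΔOM-LZ, 1 against CALM-AF10 and 1 for the averages. Fry left 0, 0, 2, 0, 3, 1 and 2 in the same order. Probe sets above the median level left 1 list for ΔOM-LZ against MIG and 8 for the minimal fusion against MIG. Other settings kept each number of lists within 1.5 times.

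Of 782 values of named genes under 14747 alternatives, 14583 stayed on their side of the threshold, 148 lost a call and 16 gained one, 0 changed sign while called, and 319 differed in sign while uncalled in both. Hoxa9 passed without any 1 array against MIG and against ΔOM-LZ, Hoxa6 in 9 and 8 of 12 fits, while Nkx2-3 and Zscan25 passed in 0 of 12 (limma adjusted p of 0.0451 and 0.0484 on all arrays). The alternative for linear values was not run, since the values are log2. How far a dim probe set stands above background is not given in the sources used here, so small changes at low log2 values may be compressed, and keeping probe sets above the median level left 6 calls for the minimal fusion against MIG.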

Other observations

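The low-oxygen list, its tests, and the test of HOXA in CALM-AF10 were chosen after the values were seen, as were the genes singled out here.

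Ankrd37 and Zscan25 separated MIG from every fusion array rather than the minimal fusion from the rest. Ankrd37 stood at 7.77, 7.44 and 7.86 in MIG arrays and between 6.47 and 6.87 in the 9 fusion arrays. Zscan25 stood at 7.74, 7.76 and 7.70 in MIG arrays and between 8.11 and 8.31 in fusion arrays. Other genes induced by low oxygen also stood lower in the fusions, without passing one by one. The collagen hydroxylase gene P4ha1 stood 0.90, 0.86 and 1.23 lower than MIG in CALM-AF10, ΔOM-LZ and the minimal fusion, with adjusted p of 0.54, 1 and 0.12. The lactate transporter gene Slc16a3 stood 1.15, 0.89 and 1.42 lower (adjusted p = 0.74, 1 and 0.37), and Bnip3, a mitophagy gene, 0.87, 1.09 and 1.62 lower (adjusted p = 0.9, 1 and 0.32). Of 30 genes induced by low oxygen, a list that holds Ankrd37 itself, 26 stood lower in all 3 fusions, with median log2 fold changes of −0.50, −0.57 and −0.55.

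Their mean score was 0.54 higher in MIG than in the fusions (SE 0.13). With the megakaryocyte, mast cell and late neutrophil scores as covariates the difference was 0.67 (SE 0.15), so these scores did not account for it. Marker scores are a partial measure of cell makeup, and other scores were not tried, so a different makeup of the MIG arrays was not excluded. Handling of the MIG cultures apart from the others, such as a denser culture, could give the same pattern, and 2 of the 3 MIG arrays lay above every fusion array (scores of 0.56, −0.01 and 0.67, against 0.08 in CALM-AF10 replicate 2), which leaves that open. An effect common to all fusions was not tested apart from handling, since no second set of control cultures was analysed here.

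Skida1 stood at 4.87, 4.74 and 4.68 in MIG arrays and 5.62, 5.83 and 6.34 in minimal fusion arrays, a log2 fold change of 1.17. It passed with trend and robust variance (adjusted p = 0.0366) and with 1 probe set per gene (adjusted p = 0.0456), and not in the fit over all probe sets tested (adjusted p = 0.0594). It lies in the chromosomal region of Mllt10 and is a little-studied gene.

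A hypothesis is that full CALM-AF10 raises HOXA genes weakly, between ΔOM-LZ and the minimal fusion. Mean HOXA scores were −0.02, −0.18 and 0.04 in CALM-AF10 arrays, −0.30, −0.30 and −0.32 in MIG arrays and −0.29, −0.37 and −0.16 in ΔOM-LZ arrays. The CALM-AF10 mean was 0.24 above that of the 6 others, with an exact two-sided permutation p of 0.024 over 84 splits, and 2 of the 3 arrays lay above all 6. These splits do not keep same-numbered CALM-AF10 and ΔOM-LZ arrays apart, so that p does not settle whether chance gave the difference. Each CALM-AF10 score lay above the ΔOM-LZ score of its number. In the paired fit the HOXA list was higher by camera (adjusted p = 0.00195), with 0.465 with an estimated correlation and 0.0783 by fry. A weak rise remains a hypothesis, and since it was tested on the arrays that prompted it, it needs new arrays.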
